A study of Drosophila melanogaster with 136 samples.

How the data were processed

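The deposited tables hold counts by the authors, raw whole numbers per gene or per miRNA arm with 1 column per library, and these were used without rescaling. The processing notes name the dm6 genome, STAR 2.4 and HTSeq without a role. The version of HTSeq, the strand setting of the counting, the read filters and the way reads were assigned to miRNAs are not given in the sources used here. S2 cells were kept at 26 °C in Schneider's medium with 10% fetal bovine serum. For RNAi, cells took up 2 µg of dsRNA in each of 2 transfections 3 days apart and were collected 4 days after the second. Poly(A) libraries were made with the NEXTflex Rapid Directional kit and read as 50-nt single ends on a HiSeq, except the RNAi set (Kapa RNA Hyperprep with mRNA capture, 50-nt paired ends, NovaSeq). Small RNA libraries started from 1 to 5 µg of total RNA, with selection between 18-nt and 32-nt markers, depletion of 2S rRNA, adapters with 4 random nucleotides and the standards cel-lsy-6 and xtr-427.

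All 136 samples fall in 62 groups, and 45 comparisons were made. Genotypes come from the sample titles, because the genotype tags of replicates carry running numbers in the gene name. The column numbered 1 of the wgn trigger line has no sample of that number and was matched by its group alone. Counted reads per library were 10.7 to 12.6 M in the S2 dora mRNA set, 11.6 to 35.5 M in the RNAi set, 10.6 to 18.3 M in the trigger lines, 9.71 to 21.9 M in dora[A], 10.2 to 28.9 M in dora[B] and 8.96 to 18.0 M in CR43432. The small RNA libraries held 1.28 to 11.5 M in S2 total RNA, 5.25 to 10.3 M in the IPs, 0.696 to 2.97 M in dora[A], 0.274 to 3.57 M in dora[B] and 0.276 to 3.19 M in CR43432. Rows that are not genes (no feature, ambiguous) were removed and made up 6.02% to 20.5% of the mRNA counts. Standards and markers made up 1.92% to 72.9% of the small RNA counts and were removed as well. That left 17477 genes, of which 17226 matched a symbol in the gene-name reference, and 310 miRNA arms, with 21 siRNA features in the IP set. Loci are those of the dm6 annotation in the RefSeq reference. Within groups no libraries were near duplicates (lowest chi-square per feature 15.95).

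The counts were fitted with edgeR (quasi-likelihood, robust, TMM scaling, features kept by filterByExpr on the groups), with 1 coefficient per group and contrasts between groups. Means over times weigh each time equally. A feature was called at an adjusted p (Benjamini-Hochberg) under 0.05, and SE is the size of the log2 fold change divided by the square root of its F statistic. Arm ratios were tested with limma (trend) on the log2 ratio of guide to passenger with 0.5 added to each count, for hairpins with a mean passenger count of at least 10. In all, 31 gene lists written from general knowledge, without external gene sets, were tested with camera (preset correlation 0.01), again with an estimated correlation, and with fry. The groups, comparisons, lists, the rule for naming genes and the alternatives, except the swapped controls of kah and ago1, were chosen before the data were examined. The p-values reflect the spread between these clones, lines and collections only.

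The rule names called genes with a mean of at least 5 CPM (50 CPM for miRNA arms) in the higher group and, outside the differences of effects, with every mutant or knockdown library on the same side of every control at each time. The most changed genes per side are then listed, 10 for mRNA, 12 higher and 8 lower for miRNAs, and 4 for trigger lines and single times. Targeted genes, triggers, their miRNAs and the 4 members of each list with the smallest adjusted p are added, and the text takes a selection of these. A named result counts as reversed under an alternative only where the sign differs and the result passes in 1 of the 2.

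The alternatives are DESeq2, RLE scaling, no filter, scaling to the 2 standards, the replicate number as a block, a fit to the compared groups alone, times summed before testing, and leaving out each library in turn. Scaling to the standards assumes 1 ratio of total RNA to standards for all libraries of a set, since the ratios per sample are in a table not used here. To see whether equal numbers mark pairs, residuals of samples sharing a number were correlated. In the RNAi set knockdowns of a clone correlated at 0.52 to 0.69 and were taken as pairs in the block alternative only. In the S2 dora mRNA set the values were -0.26 to 0.17, so there the number is not a pair. For embryos the series text and the CR43432 line numbers pair mutant and control (-0.07 to 0.67). The main fits hold no term for pairs in any set.

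In simulated counts of each design, edgeR called 82.1% of 2-fold and 97.0% of 4-fold changes in the S2 dora mRNA set, 59.7% and 95.5% for the dora[B] mRNA mean, and 67.2% and 97.0% for the CR43432 mRNA mean. The S2 kah small RNA set gave 12.5% of 2-fold changes, and mRNA contrasts at single times of the dora alleles gave 2.99% to 8.96%. Each comparison had a single draw with up to 200 changed genes or 24 changed arms, spread over 1.5-, 2- and 4-fold changes. The small RNA rates therefore rest on few arms. Splits compare the real grouping with other groupings of the same libraries, up to 100 per comparison. Software versions are 4.3.3 (R), 4.0.16 (edgeR), 3.58.1 (limma), 1.42.0 (DESeq2), 1.17.8 (data.table), 2.0.0 (jsonlite), 3.11.15 (Python), 2.4.6 (numpy) and 3.10.9 (matplotlib).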

Results

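The series measures mRNAs and small RNAs of Drosophila S2 cells and staged embryos labelled as mutants of dora or of single transcripts. Dora is the fly ortholog of ZSWIM8, a substrate receptor of a cullin-RING ubiquitin ligase that is needed for target-directed degradation of miRNAs. All 136 libraries were used. In S2 cells, poly(A) RNA was compared between 3 WT and 3 dora clones, between Ago1 and GFP knockdown in both genotypes (4 groups of 3), and between WT cells and 5 lines labelled by a trigger transcript (6 groups of 2). Small RNAs were compared in total RNA (WT, dora, kah and ago1, 3 libraries each) and after AGO1 immunoprecipitation (IP; 3 WT, 3 dora and 4 mus308 libraries). Embryos of 2 dora alleles and of CR43432 mutants stand beside wild-type controls, with 2 libraries per genotype and time, except for the single pair of CR43432 mRNA libraries at 16-20 h. The mRNA libraries hold 8.96 to 35.5 M counted reads, the S2 small RNA libraries 1.28 to 11.5 M and the embryo small RNA libraries 0.274 to 3.57 M. Changes are log2 fold changes with standard errors (SE), and levels are counts scaled to library size (CPM), given as means or per library.

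In S2 clones labelled dora, the miRNAs paired with a trigger transcript on the list of triggers were among the most increased. Of 118 arms tested in total RNA, 16 rose and 3 fell. miR-12-5p rose most (3.93, SE 0.58, adjusted p = 0.00036, 5971 against 393 CPM). It is paired with zfh1, which encodes a zinc-finger homeodomain repressor. miR-7-5p, paired with the Notch target hairy (h), rose almost as much (3.92, SE 0.37, adjusted p = 9.69e-06, 3787 against 249.5 CPM). miR-999-3p, paired with AGO1, rose by 2.63 (SE 0.55, adjusted p = 0.00399) and miR-190-5p, paired with the TNF receptor gene wgn, by 2.63 (SE 0.30, adjusted p = 3.63e-05). miR-9b-5p, paired with the zinc-finger gene Kah, rose by 2.35 (SE 0.29, adjusted p = 5.73e-05). Among arms with no listed trigger, miR-1012-3p (3.28), the seed-sharing pair miR-996-3p (2.72) and miR-279-3p (1.93), miR-9c-5p (1.82) and miR-277-3p (1.59) also rose. The 3 arms that fell were miR-278-3p (-2.54, SE 0.58, adjusted p = 0.00766), miR-1007-3p (-0.97, SE 0.29, adjusted p = 0.0343) and miR-1009-3p (-1.78, SE 0.42, adjusted p = 0.00927), the last named after its values were seen. The median over all arms was -0.10. A fit to the compared groups alone called 30 arms, and DESeq2 called 17 higher and 6 lower.

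AGO1 IP, which enriches miRNAs loaded in the effector complex, gave 36 higher and 28 lower of 136 features in dora against WT libraries (3 each). The increases of the listed miRNAs were larger relative to their SE: miR-12-5p (5.54, SE 0.16, adjusted p = 3.53e-11, 8395 against 181 CPM), miR-190-5p (4.86, SE 0.15, adjusted p = 3.53e-11, 6626 against 228 CPM), miR-7-5p (4.09, SE 0.16, adjusted p = 3.58e-10), miR-999-3p (2.74, SE 0.10, adjusted p = 1.28e-10) and miR-9b-5p (2.71, SE 0.16, adjusted p = 1.89e-08). miR-9c-5p (4.06), miR-996-3p (2.96), miR-277-3p (2.39) and miR-279-3p (1.76) rose as well. Among the arms that fell were the growth regulator bantam-3p (-0.65, SE 0.11, adjusted p = 0.000405), miR-34-3p (-0.79) and miR-282-5p (-0.95). The median over all features was -0.19, and scaling to the added RNA standards gave 48 higher and 8 lower. Of the 110 arms tested in both assays, 14 rose in total RNA and in the IP against 4.22 by chance, and 2 fell in both against 0.655. The mus308 libraries come from cells labelled for mus308, the DNA polymerase theta gene. None of the 136 features passed the edgeR test in mus308 against WT (19 at an unadjusted p under 0.05, 9 with DESeq2). In these IPs miR-12-5p gave 0.08, SE 0.13, miR-190-5p -0.14, SE 0.12, miR-7-5p -0.03, SE 0.13, miR-999-3p -0.14, SE 0.08 and miR-9b-5p 0.27, SE 0.14, adjusted p = 0.35. Scaling to the standards moved the mus308 count to 42, with 41 of these higher.

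**Figure D1:**
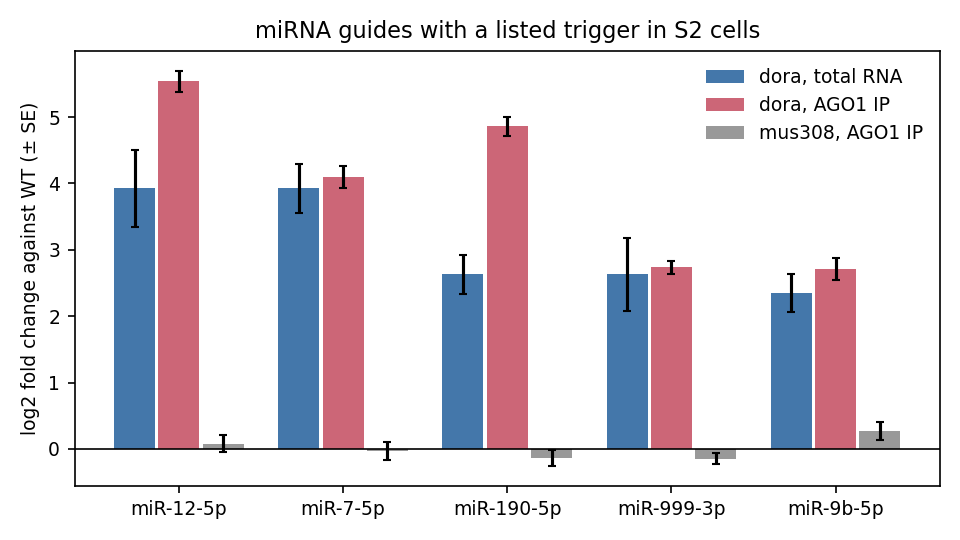
Log2 fold change against WT (y axis, log2 units) of the 5 miRNA guide arms with a listed trigger, as bars with the SE as error bars, in dora total RNA (3 against 3 libraries), dora AGO1 IP (3 against 3) and mus308 AGO1 IP (4 against 3). All 5 bars lie above 2 in the dora libraries and between -0.14 and 0.27 in the mus308 libraries.

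A miRNA that is lost after maturation should differ between guide and passenger strand, so the ratio of the arms was tested per hairpin. In dora total RNA the ratio changed for 11 of 40 hairpins, 10 of them upward. It rose for miR-7-5p (4.01, SE 0.37, adjusted p = 8.63e-07), miR-12-5p (3.22), miR-999-3p (3.13), miR-190-5p (2.70), miR-9b-5p (2.53) and miR-9c-5p (1.94). In the dora IP it changed for 23 of 38 hairpins, with 15 upward, led by miR-190-5p (5.02, SE 0.19, adjusted p = 1.49e-10) and miR-12-5p (4.87). In the mus308 IP none of 38 hairpins passed the limma test (3 at an unadjusted p under 0.05).

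In the clones labelled kah and ago1 the miRNA paired with each transcript rose. In kah clones miR-9b-5p rose (2.82, SE 0.29, adjusted p = 2.65e-05, 5661 against 803 CPM), and its arm ratio rose too (2.08, SE 0.32, adjusted p = 0.000228). In ago1 clones miR-999-3p rose (3.47, SE 0.57, adjusted p = 0.00279, 5271 against 477 CPM), with the arm ratio (5.81, SE 0.64, adjusted p = 8.07e-06). In kah clones 12 arms rose and 6 fell, among them miR-9388-5p (3.26, SE 0.48, adjusted p = 0.000482), miR-308-3p (2.29, SE 0.34, adjusted p = 0.000482), bantam-3p (0.86, SE 0.18, adjusted p = 0.00656) and, downward, miR-277-3p (-1.52, SE 0.28, adjusted p = 0.0033), a regulator of branched-chain amino acid catabolism. In ago1 clones 9 rose and 5 fell, among them miR-980-3p (4.03, SE 0.94, adjusted p = 0.0214), miR-308-3p (1.61, SE 0.33, adjusted p = 0.0116), miR-7-5p (1.16, SE 0.33, adjusted p = 0.0497), bantam-3p (0.60, SE 0.18, adjusted p = 0.0497) and, downward, bantam-5p (-1.35, SE 0.23, adjusted p = 0.00279). Arm ratios changed for 14 of 40 hairpins in kah and for 17 in ago1 (10 without ago1 replicate 1). bantam-3p, miR-308-3p and miR-9388-5p rose in both, 3 arms against 0.915 expected, and both comparisons use the same 3 WT libraries. bantam-5p was called in opposite directions (0.84 in kah). In 100 simulations of unchanged groups against these libraries no arm was called in both. Across arms the log2 fold changes correlated at 0.273 against 0.517 simulated, with a covariance of 0.282 against 0.136, so part of the excess may come from the shared controls. All 6 kah and ago1 libraries have an 18-nt to 32-nt marker ratio of 0.218 to 0.551, and the 6 WT and dora libraries one of 1.78 to 3.25, so the batch and the genotype cannot be told apart. The kah count was 37 with DESeq2 (19 higher, 18 lower), 12 with the standards (3 higher, 9 lower), 10 in a fit to its groups alone, and 7 and 8 without WT replicate 1 and 3. The ago1 count was 24 with DESeq2 (13 higher, 11 lower), 23 unfiltered, 4 with the standards (2 higher, 2 lower), 5, 2 and 2 without WT replicate 1, 2 and 3, and 8 and 4 without ago1 replicate 1 and 2. With the clones of the other label as the control, an alternative chosen after seeing the data, miR-9b-5p and miR-999-3p kept their calls while bantam-3p and miR-308-3p lost theirs. A rise shared by both labels cancels in that comparison, so this loss decides nothing about its cause.

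In poly(A) RNA the targeted gene itself was not lower at a level that passed: Dora stood at 116, 132 and 104 CPM in the 3 dora clones and 129, 132 and 121 in WT (-0.11, SE 0.11, adjusted p = 0.564). Of 7294 genes tested, 70 rose and 129 fell. The metallothionein gene MtnA (2.63, SE 0.43, adjusted p = 0.0475, 332 against 53.7 CPM), the cytochrome P450 gene Cyp6a9 (2.84, SE 0.33, adjusted p = 0.0167), the C-type lectin gene lectin-28C (2.55, SE 0.29, adjusted p = 0.0167), the segmentation gene gsb (2.73), the ecdysone-induced factor gene Eip93F (2.23), the oligopeptide transporter gene yin (1.39, SE 0.14, adjusted p = 0.00972, 920.3 against 352 CPM) and l(3)neo38 (1.80) rose. CG10184 (-4.76, SE 0.58, adjusted p = 0.0167), CG15385 (-2.50, SE 0.30, adjusted p = 0.0167, 6.03 against 34.1 CPM), the neuropeptide gene Orcokinin (-2.91) and the pheromone-sensing membrane protein gene Snmp1 (-2.57) fell. Among the trigger transcripts wgn fell (-0.84, SE 0.13, adjusted p = 0.032, 157 against 279.9 CPM). The wgn call ended without 4 of the 6 libraries in turn. Kah (-0.68, SE 0.24, adjusted p = 0.15), AGO1 (-0.23), hairy, named hry in the reference (-0.32), and zfh1 (0.05) did not pass. Of 12 glycolytic genes 4 rose, and 10 when adjusted over the list alone, among them Pfk (0.75, SE 0.11, adjusted p = 0.023), Eno (0.63) and Pgk (0.60). The list was called by camera (adjusted p = 2.45e-07), with adjusted p = 0.734 with an estimated correlation. Of 19 cell cycle and replication genes 1 fell, the replicative helicase gene Mcm2 (-0.87, SE 0.16, adjusted p = 0.0399), and 15 when adjusted over the list alone (adjusted p = 4.37e-06, and adjusted p = 0.734 with an estimated correlation). The 199 calls became 837 with DESeq2 (389 higher, 448 lower) and 383 unfiltered. Without WT replicate 1, 2 or 3 they were 15, 375 and 37, and without dora replicate 1, 2 or 3 they were 31, 14 and 49.

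Knockdown of Ago1, which encodes the Argonaute protein loaded with miRNAs, changed the largest set of genes in S2 cells. AGO1 itself fell from 739, 491 and 561 CPM to 220.1, 246 and 230.2 in WT cells (-1.39, SE 0.13, adjusted p = 7.87e-06), and in dora cells (-1.15, SE 0.13, adjusted p = 3.16e-05, 202 against 450.5 CPM). In WT cells 2013 genes rose and 2231 fell of 7861 tested, and in dora cells 1932 rose and 2095 fell. Of these, 1657 rose in both genotypes against 495 by chance, 1815 fell in both against 595, and 6 went opposite ways. Among the most increased genes were the claudin gene sinu (4.16, SE 0.16, adjusted p = 1.47e-08 in WT), Tsf2 (4.07, SE 0.15, adjusted p = 1.47e-08), Cont (3.42, SE 0.17, adjusted p = 1.3e-07), crim (3.84) and pasi1 (3.43). In dora cells Tsf2 (3.49), sinu (3.15), crim (3.44), Lac (3.06, SE 0.14, adjusted p = 6.75e-08) and the guidance cue gene Sema2a (2.96) rose. The tubulin-binding protein gene ringer fell in both (-8.88, SE 0.72, adjusted p = 5.34e-06 and -6.94, SE 0.59, adjusted p = 8.64e-06), as did betaTub97EF (-7.02 and -6.50), and the lipophorin receptor gene LpR2 fell in dora cells (-5.52, SE 0.38, adjusted p = 1.88e-06). Of 26 glutathione transferase genes 2 rose and 16 fell in each genotype, the same numbers adjusted over the list alone, with GstE7 (-3.36 in WT) and GstE6 (-2.90) among them (adjusted p = 0.000882 in WT, and adjusted p = 0.14 with an estimated correlation). All 12 glycolytic genes tested fell in both, Ldh (-4.75 in WT) and Pglym78 (-1.29) among them (adjusted p = 6.15e-05, and adjusted p = 0.414 with an estimated correlation). Of 64 oxidative phosphorylation genes 49 fell in WT and 52 in dora cells, 50 and 56 adjusted over the list alone (adjusted p = 1.65e-08 and 1.97e-10, and adjusted p = 0.752 and 0.64 with an estimated correlation).

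The trigger transcript wgn responded to the knockdown with opposite sign in the genotypes: it fell in WT (-0.36, SE 0.10, adjusted p = 0.0121) and rose in dora cells (0.61, SE 0.10, adjusted p = 0.000543). Its level was 318, 295 and 261 CPM in WT with GFP RNAi, 222, 227 and 246 in WT with Ago1 RNAi, 135, 168 and 144 in dora with GFP RNAi and 224, 251 and 225 in dora with Ago1 RNAi. The difference of the effects was 0.96, SE 0.15, adjusted p = 0.0401. The ketone-body enzyme gene SCOT (1.35, SE 0.17, adjusted p = 0.0304), the septate junction gene Lac (1.19, SE 0.18, adjusted p = 0.0401), Nepl3 (1.01) and the tetraspanin gene Tsp3A (0.76) had a higher effect in dora, and the Ly6 gene cold a lower one (-1.10, SE 0.17, adjusted p = 0.0401). These 6 genes (5 higher, 1 lower) became 130 with each clone as a block, which pairs the knockdowns of a clone, and 28 with DESeq2 (20 higher, 8 lower). Without any 1 of the 12 libraries the count was 0 to 2. Kah (0.60 and 0.74) and zfh1 (0.49 and 0.42) rose in both genotypes, and hairy (hry) fell in dora cells (-0.39, SE 0.14, adjusted p = 0.0323) and gave -0.33, SE 0.14, adjusted p = 0.0573 in WT.

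**Figure D2:**
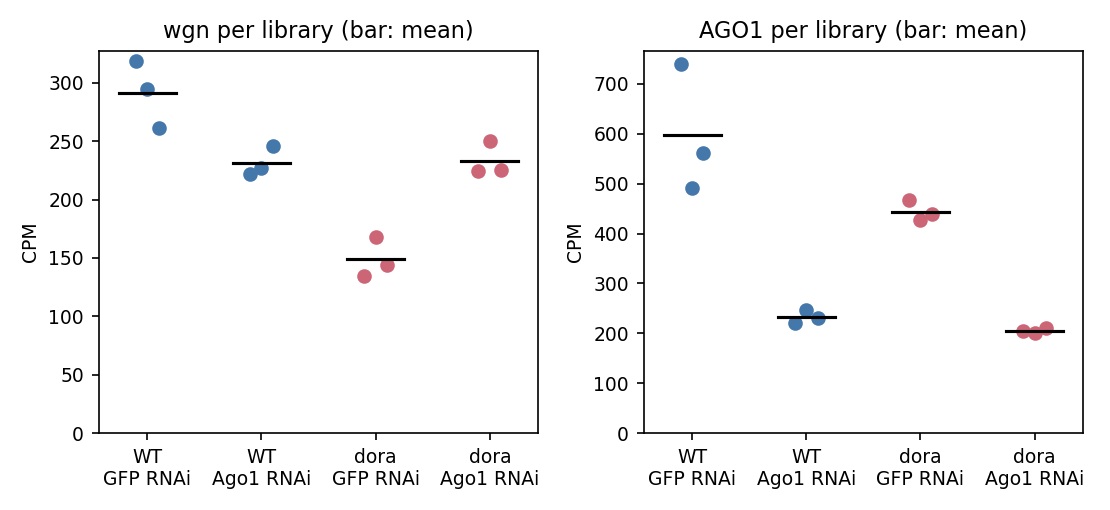
Level of wgn and AGO1 (y axes, CPM from 0) in each of the 12 RNAi libraries, with points for libraries and a bar for the mean of the 3 libraries of each group. The wgn points of dora cells with GFP RNAi lie between 135 and 168 CPM, below all other groups.

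With GFP RNAi as the only treatment, dora cells differed from WT in 93 of 7861 genes, 21 higher and 72 lower. Dora stood at 81.6, 108 and 85 CPM against 133, 136 and 136 (-0.55, SE 0.12, adjusted p = 0.0569), a difference that passed with DESeq2 and unfiltered. The changes include wgn (-0.96, SE 0.10, adjusted p = 0.00101, 151 against 294 CPM), the protein kinase A subunit gene Pka-C3 (-4.05, SE 0.78, adjusted p = 0.0479, 10.7 against 176 CPM), the threonine dehydrogenase gene Tdh (-2.74, SE 0.36, adjusted p = 0.00245), the proton pump gene Vha68-1 (-1.76), SCOT (-1.33) and the adhesion gene ed (-2.12), all lower. The sodium channel family gene ppk29 (2.45, SE 0.43, adjusted p = 0.0215), gsb (2.57, SE 0.52, adjusted p = 0.0419), stac (1.70, SE 0.18, adjusted p = 0.00101, 102 against 31.5 CPM) and the phosphatidate phosphatase gene Lpin (0.78) were higher. Of 12 apoptosis and p53 target genes 3 fell, among them the caspase gene Dronc (-1.06, SE 0.13, adjusted p = 0.00175) and hid (-3.38, SE 0.52, adjusted p = 0.00768), and adjusted over the list alone 1 rose and 4 fell (adjusted p = 0.0336, and adjusted p = 0.517 with an estimated correlation). Against the clones without RNAi, 4 genes rose in both sets where 0.191 were expected by chance, and 22 fell in both where 1.16 were expected. This expectation takes the sets as independent. Both sets number their clones alike, and if these are the same clones, differences between clones would recur in both. The 93 calls became 360 with DESeq2 (161 higher, 199 lower) and 44 in a fit to these groups alone. They were 54 and 49 without WT replicate 1 and 3, and 49 and 48 without dora replicate 2 and 3.

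In the lines labelled by a trigger (2 libraries each against 2 WT), the named transcript was lower in each case without passing the test. AGO1 stood at 535 and 619 CPM against 822 and 827 (-0.51, SE 0.17, adjusted p = 0.23), hairy (hry) at 155 and 163 against 417 and 495 (-1.53, SE 0.18, adjusted p = 0.0781) and Kah at 203 and 122 against 222 and 239 (-0.51, SE 0.41, adjusted p = 0.949). wgn stood at 175 and 266 against 339.6 and 283 (-0.50, SE 0.19, adjusted p = 0.684) and zfh1 at 2256 and 1253 against 2872 and 3111 (-0.78, SE 0.54, adjusted p = 0.672). The decrease of hairy passed with DESeq2 and unfiltered. Of 7813 genes edgeR called CG12099 in the ago1 line (-1.34, SE 0.14, adjusted p = 0.0401, 138 against 349 CPM), and in the zfh1 line the glypican gene dlp (2.94, SE 0.30, adjusted p = 0.023, 148 against 19.3 CPM) and CG7737 (-1.37, SE 0.15, adjusted p = 0.023). It called 0 in the h, kah and wgn lines (721, 386 and 553 at an unadjusted p under 0.05, and 83, 28 and 49 with DESeq2). DESeq2 called 301 in the ago1 line (178 higher, 123 lower) and 152 in the zfh1 line. In the ago1 line the count was 447 without ago1 replicate 3 and 0 without WT replicate 3, and in the zfh1 line it was 1 and 0 without WT replicate 1 and 3. In the h line it was 1 without WT replicate 1 and 2 without h replicate 2. In the kah line it was 1 without WT replicate 1, 8 without kah replicate 1 and 1 without kah replicate 3. In the wgn line it was 2 without WT replicate 1 and 1 without wgn replicate 1.

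In embryos of the dora lines mostly other miRNAs stood out: miR-309-3p, miR-3-3p and the miR-310 cluster guides, which WT embryos hold early. In S2 dora clones miR-3-3p also rose in the AGO1 IP (2.27, SE 0.325, adjusted p = 0.000124) and did not pass in total RNA (1.05, adjusted p = 0.246). miR-286-3p of its cluster rose in both (1.91, adjusted p = 0.00109 and 2.24, adjusted p = 0.0184). Other arms of that cluster in the IP, miR-6-3p among them (-0.47, adjusted p = 0.062), and miR-310-3p (-0.12, adjusted p = 0.748) did not pass. Over 8-20 h, 28 arms rose and 11 fell of 226 in dora[A], and 28 rose and 20 fell of 220 in dora[B]. The zygotic miRNA miR-309-3p, which promotes clearance of maternal mRNAs, rose most in both (3.89, SE 0.24, adjusted p = 2.68e-06 and 4.54, SE 0.21, adjusted p = 3.36e-07). miR-3-3p of the same cluster followed (2.79, SE 0.13, adjusted p = 4.97e-07 and 4.04, SE 0.18, adjusted p = 3.36e-07). Other arms of this cluster, named after their values were seen, moved less: miR-4-3p rose in dora[A] (0.43, SE 0.07, adjusted p = 0.00243) and gave 0.16 in dora[B] (adjusted p = 0.257, and 0.172 for the difference of the alleles), miR-6-3p (-0.12, adjusted p = 0.0636 and -0.19, adjusted p = 0.00549) and miR-5-3p (-0.09, adjusted p = 0.249 and -0.22, adjusted p = 0.0321) fell in dora[B], and miR-286-3p (0.36, adjusted p = 0.0656 and 0.21, adjusted p = 0.077) did not pass. Of the passenger arms miR-4-5p rose in both (0.94, adjusted p = 0.000725 and 0.87, adjusted p = 0.0247) and miR-286-5p (1.22, adjusted p = 0.00332 and 0.78, adjusted p = 0.193) and miR-5-5p (0.17, adjusted p = 0.0287 and -0.06, adjusted p = 0.69) in dora[A]. The miR-310 cluster guides, paired with the long noncoding RNA of CR43432, rose in both alleles: miR-310-3p (1.75, SE 0.18, adjusted p = 7.53e-05 and 3.52, SE 0.26, adjusted p = 9.02e-06), miR-311-3p (1.78 and 3.59), miR-312-3p (1.36 and 2.83) and miR-313-3p (1.36 and 3.12). The related miR-92a-3p (1.24 and 1.62) and miR-92b-3p (1.56 and 1.94) and miR-275-3p (1.15 and 2.53) rose as well. Of the miRNAs that stood out in S2 cells, miR-7-5p (0.74, SE 0.08, adjusted p = 0.000173 and 0.55, SE 0.08, adjusted p = 0.000774) and miR-9b-5p (0.35, SE 0.07, adjusted p = 0.0037 and 1.18, SE 0.19, adjusted p = 0.00183) rose. miR-999-3p (0.23 and 0.24), miR-12-5p (0.01 and -0.20) and miR-190-5p (-0.03 and -0.08) did not pass. Lower arms include miR-14-3p (-0.40, SE 0.06, adjusted p = 0.00186 and -0.43, SE 0.12, adjusted p = 0.0307) and miR-932-5p (-0.86 and -1.29) in both alleles, and the muscle miRNA miR-1-3p (-0.36, SE 0.06, adjusted p = 0.00242) and miR-8-3p (-0.35) in dora[B]. Across the alleles 23 arms rose in both against 3.61 by chance, and 5 fell in both against 0.922. The median over all arms was -0.12 in dora[B]. Scaling to the added RNA standards left 1 call in dora[A] and 8 in dora[B], all higher, and summing the times left 10 and 26. Without WT replicate 1 or 2 dora[A] had 20 and 18 calls, and without WT replicate 1 or mutant replicate 2 dora[B] had 24 and 30.

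By time, miR-310-3p changed by 0.91, SE 0.30 at 8-12 h, 2.13, SE 0.31 at 12-16 h and 2.22, SE 0.31 at 16-20 h in dora[A] (adjusted p = 0.222, 0.00169 and 0.00101), and by 2.02, SE 0.43, 4.35, SE 0.48 and 4.20, SE 0.47 in dora[B] (adjusted p = 0.0215, 0.000233 and 0.000297). In dora[A] 4, 17 and 24 arms changed at the 3 times (3, 16 and 22 higher), and in dora[B] 16, 29 and 31 (14, 25 and 16 higher). At 16-20 h the dora[B] median over all arms was -0.30. The log2 fold change grew from 8-12 h to 16-20 h for miR-309-3p in both alleles (3.61, SE 0.55, adjusted p = 0.00858 and 3.34, SE 0.46, adjusted p = 0.00473) and for miR-3-3p (3.10, SE 0.31, adjusted p = 0.0005 and 3.48, SE 0.41, adjusted p = 0.00244). The excess of miR-309-3p over control, not tested, did not grow. The share of WT 2-4 h RNA that would give it was 8.11, 2.69 and 2.47% at the 3 times in dora[A]. In dora[B] this share was 14.1, 8.69 and 4.54%. In dora[A] the other changes of effect were those of miR-932-5p (2.03) and miR-2b-3p (0.46). In dora[B] 4 arms had a higher effect at 16-20 h, with miR-275-3p (2.50) and miR-312-3p (2.22), and 7 a lower one, bantam-3p (-0.58, SE 0.12, adjusted p = 0.0343) among them. The numbers pair mutant and control embryos, and with each pair as a block dora[A] gave 28 and 39 arms at 12-16 h and 16-20 h and 12 changes of effect. With DESeq2 dora[A] gave 18 higher and 1 lower at 8-12 h and 21 higher and 11 lower at 16-20 h, and dora[B] 26 higher and 12 lower at 12-16 h. With RLE scaling dora[A] gave 7 calls at 8-12 h (6 higher), 17 higher and 5 lower at 16-20 h and 2 changes of effect, and dora[B] 16 higher and 6 lower at 16-20 h and 2 changes of effect (10 higher and 10 lower with DESeq2). With the standards all calls of single times ended in dora[A], and 0, 4 and 7 remained in dora[B], all higher. Without control replicate 1, mutant replicate 1, control replicate 2 and mutant replicate 2 in turn, dora[A] gave 0, 0, 0 and 20 calls at 8-12 h, 6, 10, 6 and 13 at 12-16 h, 4, 19, 13 and 18 at 16-20 h, and 0, 4, 0 and 1 changes of effect. In the same order dora[B] gave 0, 11, 6 and 10, then 9, 53, 16 and 10, then 9, 15, 14 and 22, and 0, 2, 4 and 9 changes of effect.

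The alleles differed in size of effect for 10 of 231 arms, 9 higher in dora[B]: miR-310-3p (1.66, SE 0.29, adjusted p = 0.00325), miR-311-3p (1.71, SE 0.29, adjusted p = 0.00325), miR-312-3p (1.37), miR-313-3p (1.66), miR-3-3p (1.17, SE 0.24, adjusted p = 0.00554) and miR-275-3p (1.29) among them, with miR-1-3p lower (-0.45, SE 0.09, adjusted p = 0.00427). The median over all arms was -0.15. In a single simulated draw with 24 changed arms, 28% of the calls for this difference were false, the highest share of any comparison. So few arms give no stable rate. The count was 17 with DESeq2 and 0 with the standards. It was 4 without dora[A] control replicate 1 or mutant replicate 2, 6 without dora[B] control replicate 1 and 20 without dora[B] mutant replicate 1. The arm ratio changed for 10 of 83 hairpins in dora[A] and 13 of 83 in dora[B]. It rose for miR-309-3p (3.92, SE 0.32, adjusted p = 1.66e-05 and 4.57, SE 0.47, adjusted p = 0.000292), miR-310-3p (1.46, SE 0.23, adjusted p = 0.00217 and 2.61, SE 0.37, adjusted p = 0.00158), miR-311-3p (1.51 and 1.49) and miR-312-3p (1.10 and 1.61), but not for miR-313-3p (0.00, adjusted p = 0.988 and 0.37, adjusted p = 0.142), whose passenger arm rose as well. Among other passenger arms of this cluster in dora[B], miR-311-5p (2.06, adjusted p = 0.00549) and miR-312-5p (1.18, adjusted p = 0.00242) rose too. miR-310-5p (0.68, adjusted p = 0.239) did not pass. With each pair as a block 28 hairpins changed in dora[A]. The dora[A] count was 4 and 3 without mutant replicate 1 and 2, and the dora[B] count 4 and 7 without control replicate 1 and 2 and 8 and 6 without mutant replicate 1 and 2.

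**Figure D3:**
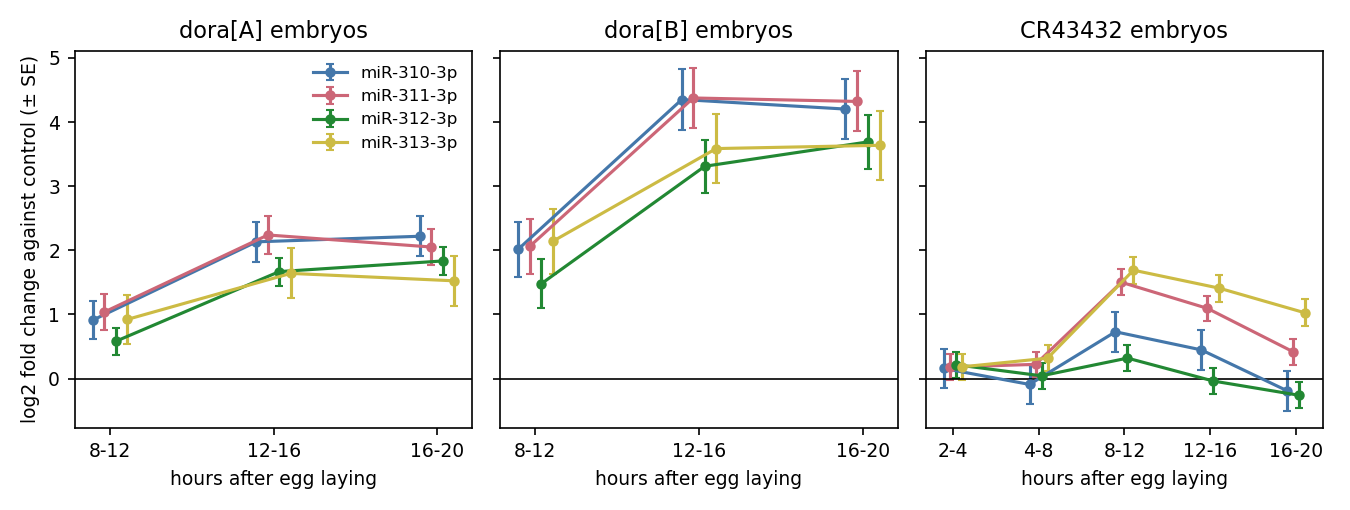
Log2 fold change against controls (y axis, log2 units, SE as error bars) of the guides miR-310-3p, miR-311-3p, miR-312-3p and miR-313-3p at each collection time (x axis, hours after egg laying) in dora[A], dora[B] and CR43432 embryos (2 against 2 libraries per point). miR-310-3p reaches 4.35 in dora[B] and 2.22 in dora[A], and stays at 0.73 or below in CR43432.

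In CR43432 embryos only part of the miR-310 cluster moved. The transcript, lncRNA:marge in the reference (dm6 3L:14976626-14977631), was not lower at a level that passed: 182 and 161 CPM in the mutants against 224 and 211 at 8-12 h, and 22.9 and 12.1 against 24.3 and 27.3 at 12-16 h (-0.46, SE 0.26, adjusted p = 1.00). Over 2-20 h, 2 of 227 arms rose, miR-313-3p (0.92, SE 0.09, adjusted p = 1.29e-05) and miR-311-3p (0.68, SE 0.09, adjusted p = 0.000172), and miR-193-5p fell (-0.85, SE 0.17, adjusted p = 0.0149), named after its values were seen. miR-310-3p (0.21, SE 0.14, adjusted p = 0.908) and miR-312-3p (0.06, SE 0.09, adjusted p = 1.00) did not pass. At 8-12 h miR-313-3p (1.69, SE 0.21, adjusted p = 0.000203, 741 against 229 CPM) and miR-311-3p (adjusted p = 0.000254, 4589 against 1622 CPM) rose. Both rose at 12-16 h (1.41, SE 0.21, adjusted p = 0.00167 and 1.09, SE 0.20, adjusted p = 0.00768), and at 16-20 h miR-313-3p (1.02, SE 0.21, adjusted p = 0.0473), where miR-311-3p gave 0.42, adjusted p = 0.993. At 2-4 h and 4-8 h miR-313-3p gave 0.18, SE 0.20 and 0.32, SE 0.20, and no arm passed in edgeR (9 and 18 at an unadjusted p under 0.05, 0 and 6 with DESeq2). Nor did any arm differ in effect between 16-20 h and 2-4 h (5 at an unadjusted p under 0.05, 0 with DESeq2). The arm ratio rose for the same guides, miR-313-3p (0.94, SE 0.07, adjusted p = 3.49e-07) and miR-311-3p (0.88, SE 0.14, adjusted p = 0.00104), of 82 hairpins, and for 1 of these without mutant replicate 1 or with a mean passenger count of at least 50. The median over all arms was -0.18 at 2-4 h. With the standards 1 call remained over 2-20 h, none at 8-12 h or later and 7 appeared at 4-8 h, and summing the times left 0. The mean lost all calls without mutant replicate 2, as did 8-12 h without either mutant replicate, 12-16 h without control replicate 1 or either mutant replicate, and 16-20 h without any 1 replicate, with RLE or unfiltered, and 4-8 h gained 4 without mutant replicate 2.

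In WT embryos of the CR43432 series, measured without a test, lncRNA:marge stood at 2.1 and 7.17 CPM at 0-2 h, 35.8 and 26.1 at 2-4 h and 6.84 in the single library at 16-20 h, and was highest at 8-12 h among the times with poly(A) libraries, which leave out 4-8 h. miR-310-3p was highest at 0-2 h (38324 and 46648 CPM) and stood at 422 and 506 at 16-20 h. miR-309-3p (32625 and 29634 CPM) and miR-3-3p (77991 and 61601 CPM) were highest at 2-4 h.

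**Figure D4:**
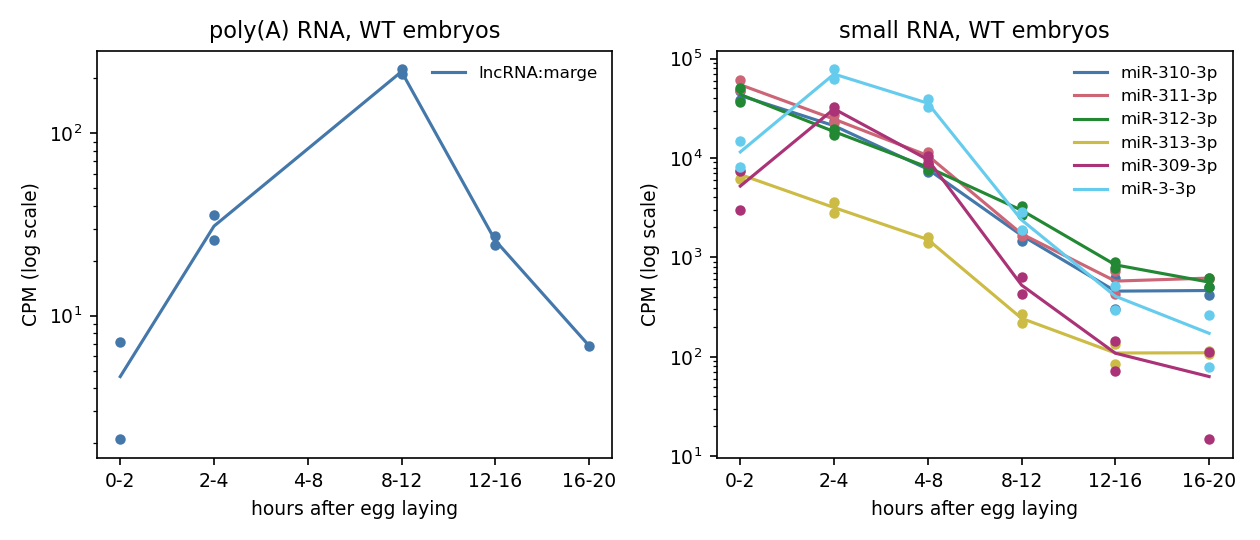
Levels in WT embryos of the CR43432 series (y axes, CPM on a log scale) of lncRNA:marge and of miR-310-3p, miR-311-3p, miR-312-3p, miR-313-3p, miR-309-3p and miR-3-3p at each collection time (x axis, hours after egg laying), with points for libraries and lines through their means. lncRNA:marge is highest at 8-12 h among its sampled times, which leave out 4-8 h.

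In poly(A) RNA of dora[A] embryos, Dora stood at 509 and 568 CPM against 618 and 737 at 8-12 h, 414 and 388 against 414 and 437 at 12-16 h and 358 and 351 against 305 and 393 at 16-20 h (-0.11, SE 0.11, adjusted p = 0.834). Of 11153 genes edgeR called 0 over the times (727 at an unadjusted p under 0.05, 18 with DESeq2). With each pair as a block it called 3, with RLE scaling 2 and unfiltered 8, and without mutant replicate 2 it called 125, 108 of them higher. At 8-12 h the cathepsin-like protease gene CtsK2 fell (-4.50, SE 0.47, adjusted p = 0.0163, 1.21 against 26.5 CPM), a call that ended without control replicate 1, mutant replicate 1 or control replicate 2. At 12-16 h and 16-20 h edgeR called 0 (520 and 245 at an unadjusted p under 0.05, 3 and 1 with DESeq2), with 13 at 12-16 h without mutant replicate 2 and 1 at 16-20 h without mutant replicate 1. In simulated data of this design a 4-fold change passed in 93.9% of genes and a 2-fold change in 62.7% for the mean.

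In dora[B] embryos the poly(A) profile changed widely. Dora was lower over the times (-0.65, SE 0.14, adjusted p = 0.00327, 364 against 551 CPM). Of 11424 genes 2028 rose and 2827 fell, with a median over all genes of -0.38. The cellularization gene slam (6.64, SE 0.49, adjusted p = 1.83e-05, 111 against 1.21 CPM), the anterior morphogen gene bcd (6.54, SE 0.56, adjusted p = 5.13e-05, 122 against 1.25 CPM), swa, needed to localize bcd mRNA (6.57, SE 0.54, adjusted p = 2.72e-05), the cytoplasmic poly(A) polymerase gene wisp (6.36, SE 0.50, adjusted p = 4.09e-05, 528 against 6.39 CPM) and plu, needed for the early embryonic cell cycles (6.53, SE 0.55, adjusted p = 1.83e-05), rose. CG15286 (-6.34, SE 0.58, adjusted p = 1.96e-05), CG18754 (-3.56), Sclp (-3.39) and CtsK2 (-2.48, SE 0.37, adjusted p = 0.000415) fell. Among the triggers zfh1 (-0.68, SE 0.11, adjusted p = 0.000725), wgn (-0.70, SE 0.18, adjusted p = 0.00988), hairy (hry, -0.77, SE 0.27, adjusted p = 0.038) and lncRNA:marge (-0.57, SE 0.18, adjusted p = 0.0283) fell, and AGO1 (-0.10) and Kah (-0.27) did not pass. At 8-12 h 763 genes rose and 22 fell, at 12-16 h 1296 and 1447, and at 16-20 h 1160 and 622, where osk, which organizes the germ plasm, rose (7.68, SE 0.99, adjusted p = 0.000842). The medians over all genes were -0.03, -0.43 and -0.48. DESeq2 gave 851 higher and 586 lower at 8-12 h and 1867 and 1268 at 12-16 h. RLE scaling gave 480 calls at 8-12 h, 1575 higher and 766 lower at 12-16 h, and 1188 and 328 at 16-20 h. Without control replicate 1 or 2 the mean count was 1677 and 1648. At 8-12 h the count was 128 and 129 without control replicate 1 and 2 and 1239 and 1284 without mutant replicate 1 and 2. At 12-16 h it was 257, 496, 4832 and 1757 in the same order, and at 16-20 h 543, 403, 964 and 4758. Mutant replicate 1 at 16-20 h stands apart, with eEF2 as its top feature (0.695% of counts) where the other poly(A) libraries of that time have bt, both named after their values were seen, and r = 0.919 to replicate 2, the lowest within any group.

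Several groups of genes moved in dora[B] over the times. Of 12 maternal transcripts on the list 7 rose and 1 fell, also adjusted over the list alone, with the RNA-binding protein gene smg (4.56, SE 0.22, adjusted p = 3.49e-06), the receptor gene tor (6.08) and the meiotic Cdc25 gene twe (6.01) higher (adjusted p = 0.000514, and adjusted p = 0.493 with an estimated correlation). Of 19 cell cycle and replication genes 13 rose and 2 fell (14 and 2 adjusted over the list alone), with CycB (4.58, SE 0.27, adjusted p = 4.52e-06), polo (3.29) and dup (2.94) higher (adjusted p = 2.28e-07, and adjusted p = 0.493 with an estimated correlation). Of 10 cullin-RING ligase genes 5 rose, Cul1 (1.22) and EloA (2.12) among them. Of 6 siRNA genes Dcr-2 (1.24) and r2d2 (1.21) rose. Of 21 muscle genes 16 fell (19 adjusted over the list alone), with Act87E (-1.11, SE 0.19, adjusted p = 0.000885), the titin-like gene sls (-0.75) and Mef2 (-0.67). Of 20 neuronal genes 15 fell and 1 rose, also adjusted over the list alone, with VGlut (-1.06) and scrt (-0.96). Of 24 chitin and sclerotization genes 12 fell (13 adjusted over the list alone), with verm (-0.89), and of 104 cuticle genes 15 fell and 1 rose (6 and 1). The medians of these 4 lists were -0.67, -0.69, -0.76 and -0.98, beside -0.38 over all genes. The camera calls from the cullin-RING list on had adjusted p = 0.00744, 0.0465, 0.00515, 0.0104, 0.00644 and 0.0104 in this order, and adjusted p = 0.493, 0.493, 0.729, 0.729, 0.729 and 0.736 with an estimated correlation. Beside these groups, 136 maternal-only genes were tested. WT embryos hold them at 20 CPM or more at 0-2 h and at 0.1 of that or less at 8-20 h. Their level at 2-4 h was not limited. Of these genes 68 rose over the times, with a median of 1.03 (1.12 with RLE scaling). The genes absent from WT embryos before 4 h were a separate set at each time (88, 296 and 774 genes). These genes had medians of -0.57, -1.26 and -1.06 at the 3 times. In dora[A] they had medians of -0.18, -0.31 and -0.34 and the maternal-only genes 0.54, 0.50 and 0.23, with 0 genes of either set called.

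**Figure D5:**
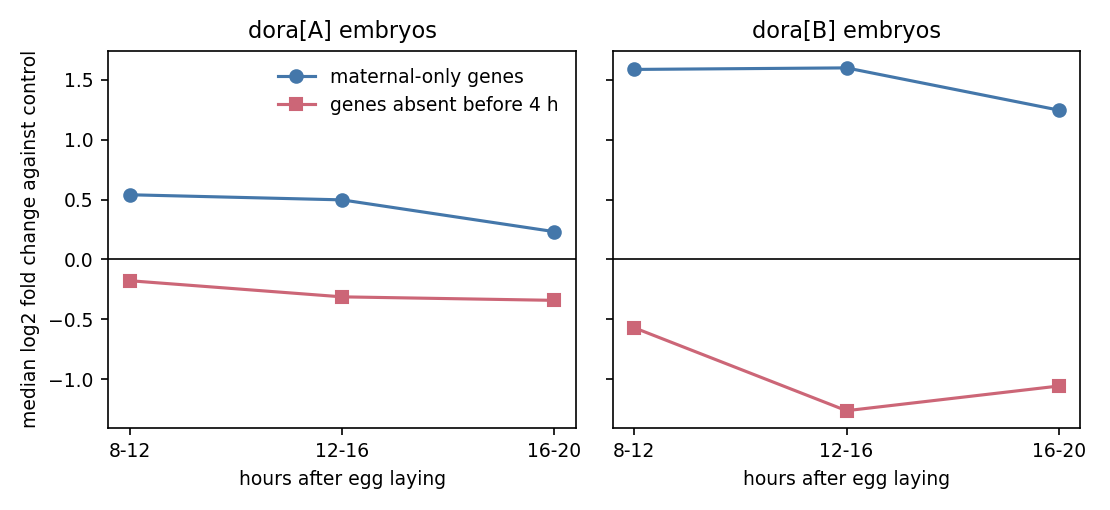
Median log2 fold change (y axis, log2 units) at each collection time (x axis, hours after egg laying) of the maternal-only genes and of the genes absent from WT embryos before 4 h (a separate set at each time), in dora[A] and dora[B] embryos (2 against 2 libraries per time). In both alleles the maternal-only genes lie above 0 and the others below 0 at all 3 times, further from 0 in dora[B].

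The dora[B] effect differed from the dora[A] effect for 1976 of 11563 genes, 1274 higher and 702 lower, with a median over all genes of -0.30. swa (5.75, SE 1.21, adjusted p = 0.00711), bcd (5.47, SE 1.27, adjusted p = 0.0114) and wisp (5.37, SE 1.24, adjusted p = 0.0106) had the higher effect in dora[B], and CG14273 (-2.18, SE 0.30, adjusted p = 0.00204), zfh1 (-0.67, SE 0.15, adjusted p = 0.00719) and Dora (-0.51, SE 0.17, adjusted p = 0.0475) the lower one. RLE scaling gave 1379 higher and 422 lower. The count was 1309 and 879 without dora[A] control replicate 1 and 2, 784 without dora[A] mutant replicate 2, and 871 and 350 without dora[B] control replicate 1 and 2.

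In poly(A) RNA of CR43432 embryos few genes changed. Over 8-12 h and 12-16 h, 5 rose and 3 fell of 10498 tested (344 at an unadjusted p under 0.05). The apical ZP-domain protein gene thw rose most clearly (3.93, SE 0.23, adjusted p = 1.25e-05, 113 against 12.3 CPM), through 8-12 h (6.94, SE 0.37, adjusted p = 5.02e-06, 184 and 169 CPM against 1.26 and 1.63), and did not pass at 12-16 h (0.92, SE 0.28, adjusted p = 0.995, 32.6 and 56.4 CPM against 25.5 and 21.8). CG15286 (2.24, SE 0.29, adjusted p = 0.0125, 49.2 against 15.5 CPM), CG6293 (2.70, SE 0.37, adjusted p = 0.0451), CG44098 (2.65, SE 0.36, adjusted p = 0.0208) and the bestrophin gene Best3 (5.35, SE 0.74, adjusted p = 0.0451) rose. The noncoding transcripts lncRNA:CR44922 (-5.32, SE 0.49, adjusted p = 0.000951, 0.885 against 18.2 CPM) and lncRNA:CR46123 (-5.29, SE 0.47, adjusted p = 0.00102, 0.224 against 8.67 CPM) and the mitochondrial P450 gene Cyp12c1 (-2.97, SE 0.33, adjusted p = 0.00336) fell. thw, CG44098, CG6293 and both noncoding transcripts lie on 3R, and Best3 and Cyp12c1 on 3L, the arm of CR43432, so all of these lie on chromosome 3. CG15286 lies on 2L. It was lower in dora[B] (-6.34) and gave -6.56, SE 0.94, adjusted p = 0.0922 in dora[A]. Whether the background of the lines accounts for these changes was not tested. At 8-12 h 2 rose and 3 fell, with CG44098 (3.92, SE 0.56, adjusted p = 0.0353), and at 12-16 h lncRNA:CR44922 (-4.17, SE 0.52, adjusted p = 0.0299) and lncRNA:CR46123 (-5.55, SE 0.67, adjusted p = 0.0299) fell. In the single mutant and control libraries at 16-20 h, not tested, thw stood at 81.2 and 98.6 CPM and lncRNA:CR44922 at 5.05 and 100.1. The counts over both times, at 8-12 h and at 12-16 h were 36, 18 and 13 with DESeq2 (8 higher and 5 lower at 12-16 h), 21, 9 and 6 unfiltered, and 0 at 12-16 h with the lines as a block, and RLE scaling gave 3 higher and 3 lower over both times. Without mutant replicate 1 or 2 they were 1, 1 and 0, and without control replicate 2 they were 26 and 25 over both times and at 8-12 h, and 4 at 12-16 h without control replicate 1.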

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

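For the maternal pattern, the tests of undeveloped eggs and of slower development acting on maternal transcripts were chosen after the result was seen, and the others before. In dora[B] embryos maternal transcripts were higher. Peak genes were chosen at 10 CPM or more at 8-12 h in WT embryos and at least 4-fold over the later times, with no libraries at 4-8 h. At 12-16 h these genes had a median of 0.29 in dora[B], or 0.72 relative to all genes, with 4 of 54 called higher and 1 lower (dora[A] 0.48 relative to all genes, 0 called). RNA from embryos under 2 h old mixed into the collections would hold the mutant excess of the maternal-only genes at 1 common ratio to WT 0-2 h embryos. A mean of 12.3% lay within 2-fold of the median, which argues against it. Slower development that held all embryos before 4 h would put genes absent before 4 h at -4 or below at 8-12 h. Their median of -0.57 argues against that for the maternal transcripts. Slower development of only some embryos would lower these genes less, was not tested and stays open. For the peak genes 0.72, most of it from the all-gene median of -0.43, is above the 0.5 set. Eggs that did not develop and aged with the collection could account for the maternal part. For transcripts that WT embryos keep to 2-4 h, the mutant excess over control had median ratios to the WT 0-2 h level of 0.495, 0.35 and 0.199 at the 3 times. For those that WT embryos clear by then the ratios were 0.00233, 0 and -0.00154. The kept transcripts spread widely (0.099 to 0.699, 0.0743 to 0.614 and 0.0532 to 0.56), so they shared no common ratio either. An effect of dora on these mRNAs in living embryos stays open as a hypothesis.

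For the embryo miRNA clusters all tests were chosen after the result was seen. The miR-310 cluster guides and miR-309-3p with miR-3-3p were higher in both dora alleles. If RNA of undeveloped eggs raised the miR-310 cluster, other arms high at 0-2 h should need the same share of it, and at the time with the fewest 85.7% of them did within 2-fold in dora[B], where it stays possible, and 57.1% in dora[A], which leaves it undecided. The median share needed was 14.4, 13.2 and 11.5% at the 3 times in dora[B], below the ratios of kept mRNAs above, and 4.27, 3.29 and 3.19% in dora[A], where kept mRNAs gave ratios of 0.0476, 0.0428 and 0.0129, and whether mRNAs and miRNAs of an egg make up the same share of their libraries was not measured. For miR-309-3p and miR-3-3p, RNA of 2-4 h embryos would raise the passenger arms of their cluster far more than seen. The median of observed minus predicted was -2.16 in dora[A] and -3.31 in dora[B], which argues against it. RNA of 4-8 h embryos is left undecided in dora[A] (-0.25, within the 0.5 set, with 12 of 15 values below the prediction). In dora[B] the median was -0.86, outside it, with 14 of 15 values below the prediction. That is short of the gap set for arguing against it, so the passenger arms leave it undecided there too. The 15 values of an allele are 5 arms at 3 times and are not independent. In dora[B] miR-6-3p made up 16.0 and 14.7% of control counts at 8-12 h and 12.7 and 12.8% of mutant counts. WT 4-8 h embryos held 19.7 and 20.1%, so their RNA would raise it. The miR-6-3p values argue against 4-8 h RNA in dora[B] at 8-12 h, for this arm only. Slower loss of guides in the dora lines, the reading by which the arm ratio was tested, stays a hypothesis, beside undeveloped eggs for the miR-310 cluster, which were not tested for miR-309-3p and miR-3-3p.

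For the arms shared by kah and ago1 clones, the test of a library batch was chosen after the result was seen, and that of chance before. bantam-3p, miR-308-3p and miR-9388-5p rose in both sets of clones, 3 arms against 0.915 expected, and bantam-5p went opposite ways. Chance shared through the common WT libraries stays open: 0 of 100 simulations of unchanged groups gave as many, but none gave any shared call, so the count was fixed and decides nothing. A library batch that kah and ago1 share could also do it, since their highest ratio of 18-nt to 32-nt marker reads was 0.551 and the lowest of the WT and dora libraries 1.78, and these data cannot tell batch from genotype. In total RNA of dora cells the same arms, named there after their values were seen, gave -0.22, -0.80 and -1.41 (adjusted p = 0.492, 0.123 and 0.0513), without a shared rise. In the dora AGO1 IP miR-9388-5p rose (2.18, SE 0.193, adjusted p = 1.38e-06). There bantam-3p fell (-0.65, adjusted p = 0.000405) and miR-308-3p did not pass (-0.20, adjusted p = 0.29).

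All comparisons with other splits of the samples were chosen after the results were seen. The real grouping alone reached its count, 1 of 100 splits, for dora[B] mRNA (4855 against 1812 in the highest other), dora[A] miRNAs (39 against 33), dora[B] miRNAs (48 against 34), the allele difference in miRNAs (10 against 7) and CR43432 miRNAs (3 against 1). It did so for 1 of 25 splits of the allele difference in mRNA (1976 against 359). Among splits that part as many pairs, the highest others were 1812 for dora[B] mRNA (29 splits), 25 for dora[A] miRNAs (28 splits), 34 for dora[B] miRNAs (31 splits) and 1 for CR43432 miRNAs (13 splits). For dora[A] mRNA all 100 splits reached the real count of 0 and another gave 123, and none of the 29 that part as many pairs called a gene, which points to a structure between pairs. For mus308 all 35 splits reached 0 features, with 1 in the highest other, and all 35 reached 0 hairpins. For arm ratios in dora[A] 2 of 100 splits reached 10 hairpins and another gave 24, which again points to sample structure, with 6 the highest of 28 parting as many pairs. In dora[B] 13 hairpins stood against 11, or 8 in the 31 splits parting as many pairs, and in CR43432 2 against 1, or 0 in 13 such splits. The other S2 comparisons with 3 libraries per group (10 splits each) and CR43432 mRNA (18 splits) have too few splits to tell.

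The Ago1 knockdown effect differed between dora and WT cells for 6 genes in the fit without pairs, and for more with each clone as a block. The miRNA effect differed between 16-20 h and 8-12 h for 4 arms in dora[A] and for 11 in dora[B]. The dora[B] and dora[A] effects differed for 1976 genes and for 10 arms. In the mus308 IPs miR-12-5p stood at 212 CPM (of total counts, without TMM) in library 2 and at 184 to 186 in the others. Chance singles out a library in about 1 in 20 such tests, and 6 features of this group of 4 were tested. The cause of these results was not tested.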

How the results depend on the processing

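With 2 or 3 libraries per group, most counts depend on single libraries, and where leaving out a library leaves a group with 1 sample, that sample is assumed to vary like the others. Scaling to the standards assumes equal ratios of total RNA to standards, and the ratio of the standards to each other was 0.384 in kah replicate 2 against 0.811 to 1.24 in the other S2 total RNA libraries. A test of target-site sets was planned and not run, because no 3′UTR sequences or genome came with the data. Of 2912 alternative values of the named results, 2380 stayed on the same side of the threshold, 505 lost a call, 25 gained one and 2 reversed. Both reversals come from the swapped controls, in which a shared rise cancels. Leaving out a library accounts for 356 of the lost calls and the standards for 59. The cause of these differences was not tested.

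With DESeq2 the count of S2 dora mRNA moved from 199 to 837, that of the knockdown difference from 6 to 28, that of GFP RNAi from 93 to 360, and those of the ago1, h, kah, wgn and zfh1 trigger lines from 1, 0, 0, 0 and 2 to 301, 83, 28, 49 and 152. In dora[A] mRNA the mean, 8-12 h, 12-16 h and 16-20 h moved from 0, 1, 0 and 0 to 18, 9, 3 and 1, and dora[B] at 8-12 h from 785 to 1437. CR43432 mRNA moved from 8 to 36 for the mean, from 5 to 18 at 8-12 h and from 2 to 13 at 12-16 h. Among small RNAs, dora[A] at 8-12 h moved from 4 to 19, the dora[B] time difference from 11 to 20, the allele difference from 10 to 17, CR43432 at 4-8 h from 0 to 6, S2 kah from 18 to 37, S2 ago1 from 14 to 24 and mus308 from 0 to 9.

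With RLE scaling dora[A] mRNA gave 2 for the mean, dora[B] mRNA 480 at 8-12 h, dora[A] small RNAs 7 at 8-12 h, the time differences 2 in each allele, and CR43432 small RNAs 0 at 16-20 h. Without a filter S2 dora mRNA gave 383, the ago1, h, wgn and zfh1 lines 7, 6, 5 and 12, dora[A] mRNA 8, 3, 1 and 1 for the mean and the 3 times, CR43432 mRNA 21, 9 and 6, dora[A] small RNAs 7 at 8-12 h, dora[B] small RNAs 14 at 16-20 h (from 31), the dora[B] time difference 2, CR43432 small RNAs 0 at 16-20 h and S2 ago1 23.

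Scaled to the standards, dora[A] small RNAs gave 1 for the mean (from 39) and 0 at each time (from 4, 17 and 24), dora[B] 8 (from 48) and 0, 4 and 7 (from 16, 29 and 31), and both time differences and the allele difference 0. CR43432 gave 1 for the mean (from 3), 7 at 4-8 h and 0 at 8-12 h, 12-16 h and 16-20 h, S2 ago1 4 and mus308 42. Times summed before testing gave 10 in dora[A], 26 in dora[B] and 0 in CR43432. Fits to the compared groups alone gave 44 for GFP RNAi, 30 for S2 dora small RNAs (from 19) and 10 for kah. A passenger count of at least 50 gave 1 hairpin in CR43432 (from 2).

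With each pair as a block, dora[A] mRNA gave 3 for the mean, dora[A] small RNAs 28 at 12-16 h and 39 at 16-20 h, the dora[A] time difference 12, CR43432 mRNA 0 at 12-16 h and dora[A] arm ratios 28 hairpins (from 10), and each clone as a block gave 130 for the knockdown difference. The block changed no other count of paired samples by more than 1.5-fold. Where samples share only a number, as the pairing check showed, a block gave 32 for S2 dora mRNA, 317 for GFP RNAi, 8 for S2 ago1 and 0 for the kah line.

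Leaving out each library in turn gave 14 to 375 for S2 dora mRNA, 0 to 2 for the knockdown difference, 48 to 89 for GFP RNAi, and 0 to 447, 0 to 2, 0 to 8, 0 to 2 and 0 to 2 for the ago1, h, kah, wgn and zfh1 lines. It gave 0 to 125, 0 to 3, 0 to 13 and 0 to 1 for dora[A] mRNA (mean and 3 times), 1648 to 5254, 128 to 1284, 257 to 4832 and 403 to 4758 for dora[B] mRNA (from 4855, 785, 2743 and 1782), and 350 to 1974 for the allele difference. CR43432 mRNA gave 1 to 26, 1 to 25 and 0 to 4. Among small RNAs, dora[A] gave 18 to 33, 0 to 20, 6 to 13 and 4 to 19, with 0 to 4 for the time difference, and dora[B] gave 24 to 66, 0 to 11, 9 to 53 and 9 to 22, with 0 to 9. The allele difference gave 4 to 20, and CR43432 gave 0 to 2 for the mean, 0 to 4 at 4-8 h, 0 to 2 at 8-12 h and 12-16 h and 0 at 16-20 h. S2 kah gave 7 to 27 and S2 ago1 2 to 16. Arm ratios gave 10 to 18 hairpins in S2 ago1 (from 17), 3 to 14 in dora[A], 4 to 8 in dora[B] (from 13) and 1 to 3 in CR43432. The Ago1 knockdowns (4244 and 4027) stayed at 3599 to 4151 in WT and 3432 to 3677 in dora cells, and the dora IP (64) at 59 to 67.

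Swapped controls were chosen after seeing the data. With ago1 clones as the control kah gave 29 arms, and with kah clones as the control ago1 gave 29. In the latter, miR-308-3p (-0.69, SE 0.32, adjusted p = 0.142) and bantam-3p (-0.25, SE 0.18, adjusted p = 0.309) reversed. Both arms rose in kah and in ago1 clones against WT, so these signs only reflect the larger rise in kah. Of 635 tests of a list in a comparison camera called 123, fry 97 and camera with an estimated correlation 0. The last called nothing anywhere, so it does not tell 1 list call from another. The fry calls lay in the Ago1 knockdowns (17 in WT and 13 in dora cells), GFP RNAi (1) and dora[B] mRNA. In dora[B] they were 18 over the times and 4, 14 and 16 at the 3 times, with 14 for the allele difference.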

Other observations

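In dora[B] embryos, whose median over all genes was -0.38 over the times, genes of the energy-producing pathways lay little below that median: 30 of 66 oxidative phosphorylation genes fell, as many adjusted over the list alone (median -0.45, adjusted p = 0.00515, and adjusted p = 0.729 with an estimated correlation), and 9 of 12 glycolytic genes (10 adjusted over the list alone, median -0.57, adjusted p = 0.0338, and adjusted p = 0.729 with an estimated correlation). Of 20 genes of the miRNA and mRNA decay machinery 9 rose and 3 fell (10 and 5 adjusted over the list alone, adjusted p = 0.00744, and adjusted p = 0.565 with an estimated correlation). In the S2 dora IP, of 10 endogenous siRNA features of the long hairpin transcripts CR18854 and CG4068, 7 rose, CR18854_2 (2.50, SE 0.31, adjusted p = 3.88e-05) and CG4068_2 (1.42, SE 0.19, adjusted p = 6.36e-05) among them, and CG4068_3, named after its values were seen, fell (-1.39, SE 0.29, adjusted p = 0.00159).

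In several sets a list was called by camera while none of its genes passed alone, and fry called 0 lists in each of these comparisons. In CR43432 embryos at 12-16 h the 78 cuticle genes had a median of 0.99 (12 rose adjusted over the list alone, adjusted p = 4.51e-29, and adjusted p = 0.255 with an estimated correlation), and 17 digestive enzyme genes one of 0.79 (0 adjusted over the list alone, adjusted p = 4.61e-08, and adjusted p = 0.111 with an estimated correlation). In dora[A] over the times the respiratory genes had a median of -0.18 (adjusted p = 0.000628, and adjusted p = 0.727 with an estimated correlation), and the cell cycle genes one of 0.47 (adjusted p = 0.00112, and adjusted p = 0.727 with an estimated correlation), with 0 genes of either adjusted over the list alone. In S2 dora clones ribosomal protein genes had a median of 0.23 (0 adjusted over the list alone, adjusted p = 2.45e-07, and adjusted p = 0.734 with an estimated correlation). Among trigger lines, heat shock genes in the h line (-2.37, adjusted p = 2.03e-05, and adjusted p = 0.675 with an estimated correlation), ribosomal protein genes in the kah line (-0.20, adjusted p = 5.03e-13, and adjusted p = 0.737 with an estimated correlation) and glycolytic genes in the zfh1 line (-0.51, adjusted p = 1.0e-05, and adjusted p = 0.771 with an estimated correlation) had low medians, with 0, 0 and 1 genes lower adjusted over the list alone.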
